A study of Homo sapiens with 4 samples.

How the data were processed

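The series holds 4 libraries of total RNA, 1 each for DU145 with DMSO, DU145 with 120 µM OICR-9429, PC-3 with DMSO and PC-3 with 150 µM OICR-9429, all taken at 48 h. Groups, doses and times were taken from the labels. The labels name separate media for the lines, so dose and medium both differ with the line.

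The authors deposited, per library, Ensembl gene identifiers with values in CPM, per the file headers. The submitters' processing notes name bcl2fastq 2.19.1, HISAT2 2.1.0, HTSeq 0.6.1 and the genome build hg19, with no role or order. The gene annotation is not given in the sources used here. Each CPM value was a whole multiple of 1 step per library (100% of values within 0.01 step), so whole reads were recovered. The recovered counts were even, except values of exactly 1 step (111, 519, 190 and 313 values, in the order of libraries above). Those 1-step values occurred only where the other library of that line had at least 10 reads, so they were taken to stand for 0. Counting errors were based on fragments, with 2 reads each, which gave 27591000, 28444000, 29312000 and 27798000 fragments to the nearest 1000. At this depth 3 fragments correspond to 0.109, 0.105, 0.102 and 0.108 CPM. Genes that would be at 0 in one library and low in the other were not listed, so a gene that is not listed has no value here. PCR copies cannot be told from independent molecules, and intervals cover counting error only.

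Of 27658 identifiers, 27302 were named by current symbols, 191 by GENCODE 29 alone and 165 had no name. The reference at hand was on another build than hg19, so no coordinates are given. It served for names, gene types, and the length and GC content of transcripts (99.4% of identifiers). HTSeq's settings for strand and shared reads are not given in the sources used here, so genes with near-identical copies or overlaps (ribosomal proteins, HSPA1A and HSPA1B, histones, metallothioneins) are uncertain.

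The design had foreseen raw counts. Since the deposited unit is CPM, the branch written for normalized values was used and count tests became alternatives. Within a line, changes are differences of log2(CPM + 1), and a gene was counted when the change was at least 2-fold and the higher library had at least 1 CPM. This is a rule of size with no test. Ratios have exact conditional binomial 95% intervals, which compare the 2 libraries and not the conditions. Across lines, limma 3.58.1 with trend was fitted to log2(CPM + 1) with line and treatment as terms, on the 14976 genes over 1 CPM in at least 2 libraries. The fit has 1 residual degree of freedom and a prior of 12.8 degrees of freedom, and p-values were adjusted by Benjamini-Hochberg at 0.05. Its p-values and standard errors rest on a variance moderated toward the trend over all genes. A gene's own difference between the 2 lines gives 1 degree of freedom, against 12.8 from the prior. They therefore reflect mostly the trend, and little of the gene's own spread between these lines.

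Lists fixed before the data were examined covered WDR5 complexes, cell cycle, repair, apoptosis, immune, stress, xenobiotic, lipid, lysosomal, ribosomal, energy, lineage, platinum transport, androgen receptor, histone and immediate early genes, with markers of other cell types. The median of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries, and said to stand apart under the 2.5th or over the 97.5th percentile. Genes named in the text follow a rule set before the data were examined: the 10 highest and 10 lowest per line among genes past the size rule with at least 5 CPM, the 10 highest and lowest by the smaller change in both lines, up to 4 members per list, the 5 most opposite genes, and WDR5, CD274, CTNNA1, AURKA, CCNB1, E2F1, CCNE2, UHRF1, BIRC5 and XRCC2. Members of a list were ranked by the absolute mean of their changes in the 2 lines, which favours large changes and members that moved alike. CDC25B was named after its values were seen, as were the interferon and sensor genes of the closing section and some ribosomal protein genes labelled in their plot. Some genes that the rule names, and lists that rest on them, are not reported here.

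The cross-line test was tested on simulated data at a dispersion of 0.111. It recovered 4 of 100 genes changed 2-fold and 59 of 100 changed 4-fold. Beside these right calls it made 5 false ones (14976 genes simulated). The simulated genes shared 1 dispersion and changed alike in both lines, which the data need not do. The list percentile in DU145 called 3 of 100 unshifted random lists and 100 of 100 lists of 30 genes shifted by 0.5. The unshifted lists were themselves random draws, so their low rate of calls follows from the procedure. It does not carry over to lists whose genes move together.

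Alternatives were median-of-ratios scaling, a pseudocount of 0.1, a minimum of 5 CPM, list members over 5 CPM, DESeq2 1.42.0 and limma-voom on the recovered fragments, limma without trend, no filter and no line term. TMM scaling and edgeR 4.0.16 on the recovered fragments, which the design had named for raw counts, were added as alternatives after the data were seen. So were random lists matched also on length and GC content. Computation used R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.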

Results

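RNA sequencing measured gene expression in 2 human prostate cancer cell lines, DU145 and PC-3, after 48 h with OICR-9429 or with its solvent DMSO. OICR-9429 is a small molecule that binds WDR5, a WD-repeat adaptor protein of histone methyltransferase complexes, and blocks its interaction with MLL. The dose was 120 µM in DU145 and 150 µM in PC-3. DU145 and PC-3 were both derived from metastases and grow without androgen. Each of the 4 combinations of line and treatment had 1 library, so a difference within a line has no replicate check. To the nearest 1000, the libraries held 55181000 reads (DU145, DMSO), 56888000 (DU145, OICR-9429), 58623000 (PC-3, DMSO) and 55596000 (PC-3, OICR-9429), as recovered from the deposited values. Values were given for 25338 genes in DU145 and 23313 in PC-3. Mitochondrially encoded genes took 5.63% and 5.54% of the DU145 reads (DMSO, then OICR-9429) and 6.38% and 6.14% of the PC-3 reads. All values are read counts scaled to the library total (CPM), all changes are differences of log2(CPM + 1), OICR-9429 minus DMSO, and all ratios of CPM carry an exact 95% interval that covers counting error only. Because 1 CPM is added, the log2 change of a low gene is smaller than that of its CPM.

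CTNNA1, which encodes alpha-catenin and is deleted in PC-3, checked the line labels. It stood at 499 and 656 CPM in DU145 (DMSO, then OICR-9429) and at 2.73 and 3.45 CPM in PC-3.

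The study asked how WDR5 bears on chemoresistance and on PD-L1. WDR5 (ENSG00000196363) itself stood at 88.8 CPM with DMSO and 83.5 CPM with OICR-9429 in DU145, a ratio of 0.940 (0.888 to 0.995). In PC-3 it stood at 62.2 and 37.6 CPM, a ratio of 0.604 (0.559 to 0.652). CD274 (ENSG00000120217), which encodes PD-L1, stood at 27.4 and 29.2 CPM in DU145, a ratio of 1.07 (0.966 to 1.18), which includes 1 on the deposited scale. TMM and median-of-ratios scaling raise DU145 ratios by 0.17 and 0.24 on the log2 scale. The direction of WDR5 in DU145, and whether the CD274 interval there includes 1, therefore depend on the scale. In PC-3 CD274 stood at 18.5 and 9.50 CPM, a ratio of 0.515 (0.442 to 0.597), which is short of the 2-fold rule on the log2(CPM + 1) scale at −0.89. Neither gene passed the test across both lines (limma, Benjamini-Hochberg adjusted p = 0.83 for WDR5 and 0.90 for CD274). Of the 24 members of WDR5-containing complexes, 0 differed by 2-fold in either line. Their median was −0.03 in DU145, where it turned to 0.21 under median-of-ratios scaling, and 0.10 in PC-3. The immune checkpoint ligands had medians of −0.05 in DU145 (1 of 15 lower by 2-fold, 0 higher) and −0.04 in PC-3 (2 of 18 higher, 1 lower). Among them HMGB1, a chromatin protein and danger signal, stood at 429 and 158 CPM in PC-3, and NT5E, the ectonucleotidase CD73, at 394 and 741 CPM in DU145.

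**Figure D1:**
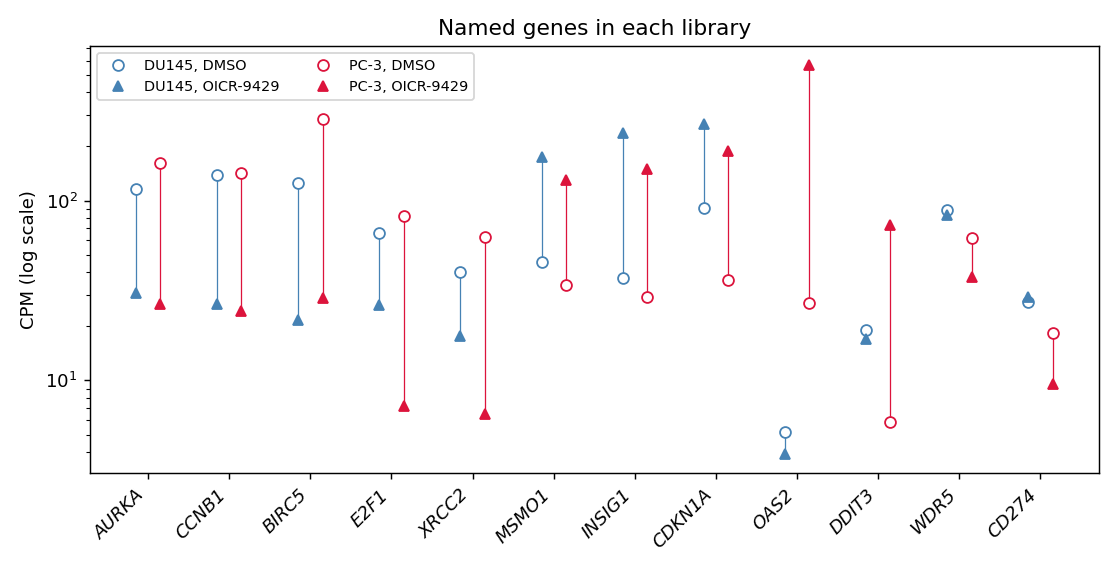
CPM (log scale) of 12 genes in each of the 4 libraries, with open circles for DMSO and filled triangles for OICR-9429, joined within a line. BIRC5 went from 125 to 21.7 CPM in DU145 and from 285 to 28.6 CPM in PC-3, OAS2 from 26.9 to 564 CPM in PC-3, and WDR5 from 88.8 to 83.5 CPM in DU145.

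In DU145 the genes of cell division stood lower and those of sterol synthesis higher with OICR-9429. Among 39 genes of G2/M and mitosis, 38 were lower by at least 2-fold, with a median of −2.19. AURKB, a mitotic kinase, went from 64.6 to 7.45 CPM, NEK2, a centrosomal kinase, from 67.1 to 7.56 CPM, and CENPA, the centromeric histone H3 variant, from 42.7 to 4.68 CPM. Of 40 genes of DNA replication and G1/S, 14 were lower by 2-fold and 0 higher (median −0.81), and of 30 genes of homologous recombination and Fanconi anaemia repair, 13 were lower and 0 higher (median −0.93). Of 24 cholesterol synthesis genes, 21 were higher by 2-fold, with a median of 1.36. INSIG1, which retains the SREBP regulator in the endoplasmic reticulum, went from 37.3 to 237 CPM, HMGCS1, an enzyme of the mevalonate pathway, from 75.9 to 446 CPM, and IDI1, an enzyme of the same pathway, from 55.4 to 252 CPM. Fatty acid synthesis genes had a median of 0.94 (5 of 12 higher), among them SCD, a desaturase, with 659 and 2404 CPM, and FASN, the fatty acid synthase, with 292 and 1115 CPM.

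Ribosomal protein genes stood lower in the treated DU145 library. The 46 genes of the large subunit had a median of −1.02 (25 lower by 2-fold, 0 higher) and the 32 of the small subunit a median of −0.46 (10 lower, 0 higher), both below all of the matched random lists. Under median-of-ratios scaling the medians were −0.79 and −0.22 and under TMM −0.87 and −0.30. They stayed below all of the random lists, but 1 factor moves genes and random lists nearly alike, so this placement adds no support. RPL36 stood at 200 and 64.0 CPM and RPL29 at 463 and 158 CPM. Ribosomal protein genes share sequence with many processed pseudogenes, so the level of each is uncertain. Glycolysis and hypoxia genes had a median of 0.51 (6 of 26 higher, 0 lower), with HK2, a hexokinase, at 28.0 and 83.9 CPM and ANGPTL4, a lipase inhibitor, at 12.0 and 63.0 CPM. NRF2 targets had a median of 0.43 (1 of 23 higher, 0 lower), the higher member being NQO1, a quinone reductase, at 454 and 978 CPM, and heat shock genes a median of 0.30 (1 of 17 higher, 0 lower). Epithelial markers had a median of −0.46 (4 of 19 lower, 1 higher), with CDH1, the epithelial cadherin, at 58.4 and 23.4 CPM. Outside these lists, the largest changes included TXNIP, a thioredoxin-binding protein, from 59.6 to 4.68 CPM, SUSD2 from 131 to 16.7 CPM, ENPP2, which encodes autotaxin, from 9.64 to 0.387 CPM, DUSP6, a phosphatase of ERK, from 19.0 to 108 CPM, PHLDA2 from 19.2 to 90.6 CPM, and LIPG, which encodes endothelial lipase, from 2.83 to 18.2 CPM.

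**Figure D2:**
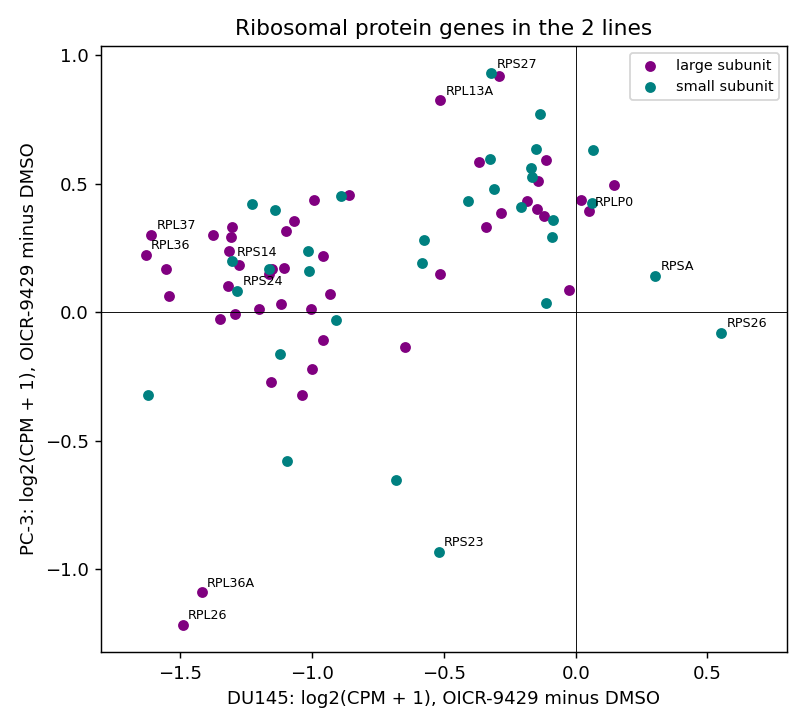
Log2(CPM + 1) change of the 78 ribosomal protein genes with OICR-9429 in DU145 (horizontal axis) and PC-3 (vertical axis), 1 point per gene, coloured by subunit. The DU145 medians were −1.02 for the large and −0.46 for the small subunit, and the PC-3 medians 0.22 and 0.29.

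By the rule of size, 1452 DU145 genes differed by at least 2-fold, 161 higher and 1291 lower. The higher share was 11.1% on the deposited scale, 22.1% under TMM scaling (251 higher, 883 lower) and 30.03% under median-of-ratios scaling (327 higher, 762 lower), since these raised the treated over the DMSO library by 0.17 and 0.24 on the log2 scale. Genes over 1 CPM in the DMSO library had a median change of −0.19 in DU145, and all listed genes one of −0.11. The lower abundance classes carried this shift: summed CPM of genes at 1 to 10 CPM was 0.702 times the DMSO value, against 1.05 times for genes over 100 CPM. Median changes were −0.38 at a mean of 1 to 10 CPM, −0.12 at 10 to 100 CPM and 0.08 over 100 CPM. The values above are to be read against genes of like level.

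In PC-3 the genes of DNA replication and cell division stood lower and those of the interferon response higher with OICR-9429. All 40 genes of DNA replication and G1/S were lower by 2-fold, with a median of −2.47, as were 38 of 39 genes of G2/M and mitosis (median −2.95), the exception being CDC25B. RRM2, a subunit of ribonucleotide reductase, went from 138 to 3.85 CPM, UHRF1, a reader of hemimethylated DNA, from 242 to 7.48 CPM, MCM10, a replication initiation factor, from 34.3 to 1.19 CPM, and MKI67, the proliferation marker Ki-67, from 472 to 28.7 CPM. Homologous recombination and Fanconi anaemia genes had a median of −1.54 (16 of 30 lower, 0 higher), with XRCC2, a recombination factor, at 62.9 and 6.48 CPM. All 35 interferon-stimulated genes were higher by 2-fold, with a median of 3.12. RSAD2, the antiviral enzyme viperin, went from 1.09 to 99.8 CPM, a ratio of 91.4 (64.6 to 134), MX1, an antiviral GTPase, from 20.3 to 463 CPM, and OAS2, an oligoadenylate synthetase, from 26.9 to 564 CPM. In DU145 the same list had a median of −0.28, with 2 of 35 lower and 0 higher, and MX1 stood at 55.4 and 39.5 CPM. MHC class I antigen presentation genes had a median of 1.13 in PC-3 (9 of 17 higher, 0 lower), with B2M, the MHC class I light chain, at 623 and 1360 CPM and TAP1, a peptide transporter, at 38.0 and 125 CPM.

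The medians of the stress lists differed in PC-3, a difference that was not tested. Heat shock genes had a median of −0.34 but a mean of 0.07, with 4 of 18 higher and 2 lower. Their list no longer stood apart under 2 alternatives. Integrated stress response genes had a median of 1.38 (20 of 31 higher, 0 lower), with DDIT3, which encodes CHOP, at 5.90 and 73.2 CPM and TRIB3, a pseudokinase, at 109 and 967 CPM. Chaperone and unfolded protein response genes had a median of 0.48 (5 of 23 higher), with ERN1, the sensor IRE1, at 63.6 and 469 CPM. Autophagy and lysosome genes had a median of 0.80 (9 of 23 higher), with SQSTM1, an autophagy receptor, at 500 and 3126 CPM, and NRF2 targets a median of 0.55 (8 of 23 higher), with FTH1, the ferritin heavy chain, at 1647 and 8426 CPM. CDK inhibitor genes had a median of 0.62 (6 of 14 higher, 1 lower), with CDKN2B at 54.0 and 423 CPM. Pro-apoptotic genes had a median of 0.33 (4 of 23 higher), and BMF and PMAIP1, which encode BH3-only proteins, stood at 13.4 and 142 CPM and at 38.5 and 105 CPM. The pro-apoptotic list no longer stood apart with a pseudocount of 0.1, at the 97.3th percentile. Ribosome biogenesis genes had a median of −0.74 (10 of 29 lower, 0 higher), with NOLC1, a nucleolar protein, at 243 and 92.7 CPM. Glycolysis and hypoxia genes had a median of −0.28 (8 of 27 lower, 1 higher), with PDK1 at 64.9 and 21.7 CPM and NDRG1, the 1 higher member, at 453 and 2094 CPM.

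By the rule of size, 2316 PC-3 genes differed by at least 2-fold, 1046 higher and 1270 lower.

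**Figure D3:**
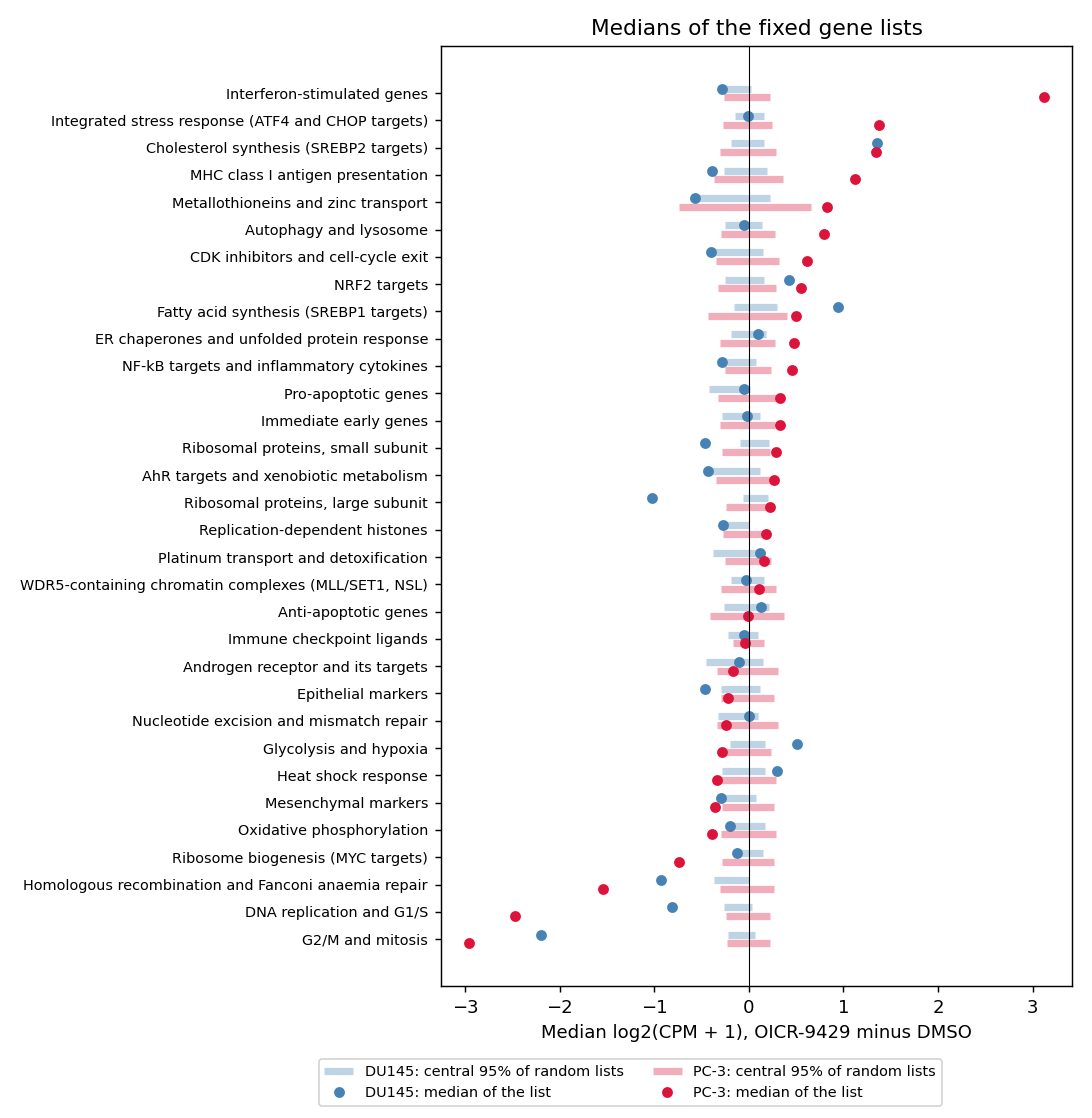
Median log2(CPM + 1) change (horizontal axis) of 32 gene lists fixed beforehand in DU145 (blue) and PC-3 (red), with bars for the central 95% of 10000 random lists matched on expression. The medians of G2/M and mitosis were −2.19 and −2.95, those of cholesterol synthesis 1.36 and 1.34, and those of interferon-stimulated genes −0.28 and 3.12.

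The responses of the lines were set side by side to ask which changes they shared. Of the 20993 genes measured in both, 13566 had at least 1 CPM in a library of each line and were compared. Across these, the log2 changes had a Pearson correlation of 0.25 and a Spearman correlation of 0.14 (across genes, which are not independent replicates). By the rule of size 38 genes were higher in both lines, against 9.41 for independent lists, and 313 were lower in both, against 72.1. A further 15 genes were higher in DU145 and lower in PC-3 (11.5 for independent lists), and 49 lower in DU145 and higher in PC-3 (59.2). The count of 15 became 27 with a pseudocount of 0.1 (20.1 for independent lists) and 29 under median-of-ratios scaling (24.2). The last count was 154 with a pseudocount of 0.1 (119 for independent lists) and 28 under median-of-ratios scaling (37.7).

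With line as the unit of replication, 18 genes rose and 173 fell across both lines among 14976 tested (limma with trend, adjusted p under 0.05). Of the 39 genes of G2/M and mitosis 36 fell (38 when adjusted over the list alone). AURKA fell by 2.23 ± 0.31 on the log2 scale (SE, limma, adjusted p = 0.0017), CCNB1, which encodes cyclin B1, by 2.41 ± 0.30 (adjusted p = 0.0011) and CDK1, the mitotic cyclin-dependent kinase, by 3.03 ± 0.34 (adjusted p = 0.00098). BIRC5, which encodes the apoptosis inhibitor survivin, fell by 2.87 ± 0.32 (limma, adjusted p = 0.00098). Of the 40 genes of DNA replication and G1/S 14 fell (38 adjusted over the list alone), among them RRM2, E2F1, a transcription factor of S-phase entry (−2.32 ± 0.43, limma, adjusted p = 0.014), and UHRF1 (−2.78 ± 0.63, limma, adjusted p = 0.049). Each estimate is an average over the lines. In DU145 26 of the 40 replication genes were under 2-fold, while in PC-3 all 40 were lower by 2-fold. For UHRF1 most of the average came from PC-3. CCNE2, which encodes cyclin E2, did not pass (−0.91 ± 0.49, limma, adjusted p = 0.67), with 5.80 and 5.77 CPM in DU145 and 15.9 and 3.81 CPM in PC-3. Of the 30 homologous recombination and Fanconi anaemia genes 10 fell (18 adjusted over the list alone), among them FANCD2, FANCI, EXO1 and XRCC2 (−2.12 ± 0.45, limma, adjusted p = 0.031).

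Of the 24 cholesterol synthesis genes 9 rose (23 adjusted over the list alone). INSIG1 rose by 2.48 ± 0.30 (SE, limma, adjusted p = 0.00098) and MSMO1, a sterol oxidase, by 1.92 ± 0.30 (adjusted p = 0.0037). Of the 12 fatty acid synthesis genes ACSS2, an acetyl-CoA synthetase, rose (5 of 12 adjusted over the list alone). CDKN1A, which encodes the CDK inhibitor p21, rose by 1.95 ± 0.32 (limma, adjusted p = 0.0051) and MMP1, an interstitial collagenase, by 2.63 ± 0.43 (adjusted p = 0.0049). PCYT2, an enzyme of phosphatidylethanolamine synthesis, MXD1, an antagonist of MYC, and NEU1, a lysosomal sialidase, also rose. ATP6V0D2, a subunit of the vacuolar proton pump, rose by 2.31 ± 0.39 (limma, adjusted p = 0.0067), from 0.0725 to 2.46 CPM in DU145 and from 0.171 to 7.95 CPM in PC-3, with few fragments in the DMSO libraries. Of the 34 interferon-stimulated genes tested 0 passed over all genes with limma or with edgeR (20 at an unadjusted p under 0.05 with limma, and 17 passed when adjusted over the list alone, an average over the lines that comes from PC-3). These calls depend on the fit. edgeR on the recovered fragments called 3 genes higher and 37 lower, and the fit without a line term called 0 (230 at an unadjusted p under 0.05). With edgeR 17 of the G2/M genes fell, 0 of the replication genes (36 at an unadjusted p under 0.05), 0 of the recombination and Fanconi anaemia genes (18), and 1 cholesterol and 0 fatty acid synthesis genes (22 and 6) rose. Under TMM scaling the counts were 30, 1, 3, 3 and 0. Of the genes named here as rising or falling, CCNB1, CDK1, BIRC5, INSIG1, MMP1 and ATP6V0D2 passed with edgeR too (adjusted p = 0.046), and ATP6V0D2 did not pass under TMM scaling (adjusted p = 0.059). The others did not pass with edgeR, among them AURKA (adjusted p = 0.065), CDKN1A (0.082), E2F1 (0.24), XRCC2 (0.30) and UHRF1 (0.57).

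**Figure D4:**
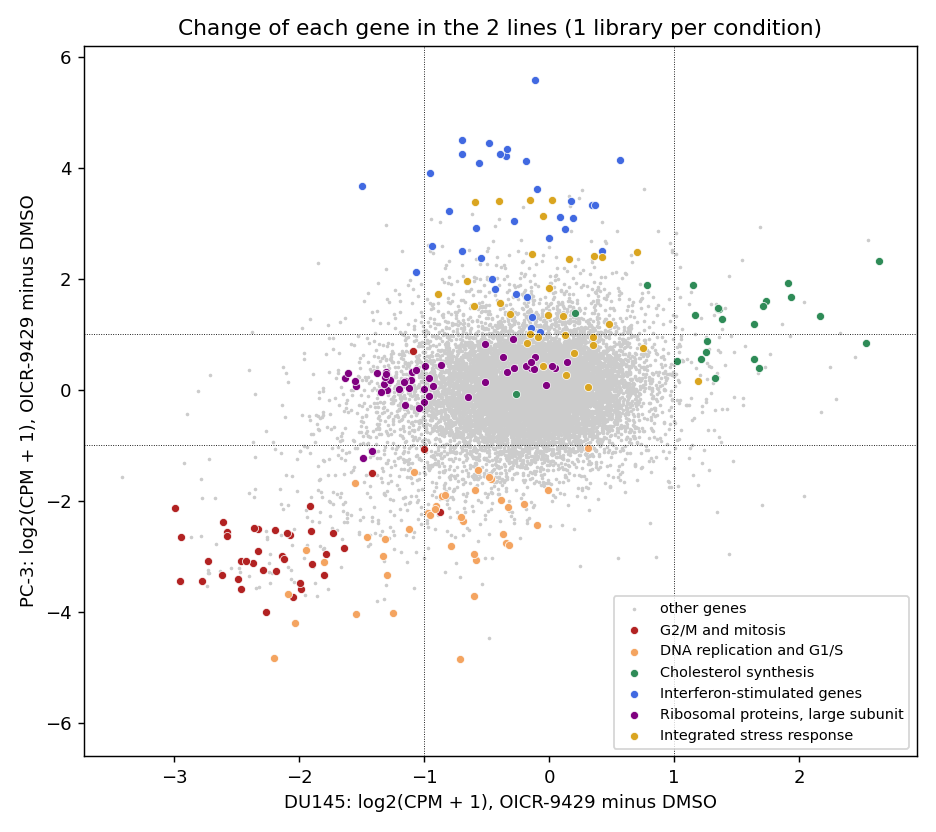
Log2(CPM + 1) change with OICR-9429 in DU145 (horizontal axis) and PC-3 (vertical axis), 1 point per gene with at least 1 CPM in a library of each line, with members of 6 lists in colour and dotted lines at 2-fold. Mitotic genes lie at the lower left (38 of 39 past 2-fold in each line), cholesterol synthesis genes at the right and interferon-stimulated genes along the top (35 of 35 past 2-fold in PC-3).

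Oxidative phosphorylation genes had medians of −0.20 in DU145, which turned to 0.045 under median-of-ratios scaling, and −0.39 in PC-3, with 0 of 25 past 2-fold in either line. Both medians stood apart from random lists, as lower, under each alternative too. Under another scaling that placement was nearly fixed beforehand, since 1 factor moves the list and the random lists together. In DU145 it therefore means lower than genes of like level only. Nucleotide excision and mismatch repair genes had medians of 0.00 and −0.24, with 2 and 5 of 21 lower, and neither median stood apart. Anti-apoptotic genes had medians of 0.13 and 0.00, with BIRC5 the member that fell across both lines. No member of platinum transport and detoxification differed by 2-fold in either line (medians 0.12 and 0.17). Mesenchymal markers had medians of −0.30 and −0.35 (5 of 22 and 8 of 26 lower), and in PC-3 the median was −0.08 over members above 5 CPM, no longer apart from random lists. Epithelial markers in PC-3 had a median of −0.22. NF-kB targets had medians of −0.28 and 0.45 (1 of 28 higher and 6 lower in DU145, 5 of 29 higher and 4 lower in PC-3), and CXCL6, a chemokine, fell across both lines with limma (−1.83 ± 0.38, adjusted p = 0.030) but did not pass with edgeR (adjusted p = 0.064). Heat shock genes in PC-3 had a median of −0.34 but a mean of 0.07, with 4 of 18 higher and 2 lower, among them HSPB1 at 333 and 115 CPM. CDK inhibitor genes in DU145 had a median of −0.40. AhR targets had medians of −0.43 and 0.27, metallothioneins and zinc transport −0.57 and 0.83, androgen receptor targets −0.10 and −0.17, replication-dependent histones −0.27 and 0.18, and immediate early genes −0.01 and 0.33. Of these, the PC-3 medians of metallothioneins and of immediate early genes stood apart from random lists. The DU145 medians of the integrated stress response (−0.01), chaperones (0.10), autophagy (−0.05), ribosome biogenesis (−0.13) and pro-apoptotic genes (−0.05) lay within the central range. Under median-of-ratios scaling those of the stress response, autophagy, ribosome biogenesis and pro-apoptotic genes turned to 0.22, 0.19, 0.12 and 0.17, and those of immediate early genes and androgen receptor targets to 0.12 and 0.03. Leukocyte and stromal markers had medians of −0.22 and 0.10, and 0 of 9 and 0 of 8 differed by 2-fold.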

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

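The list medians and single genes here went one way in DU145 and the other way in PC-3, which need not hold for each member of a list. Flagged were the lists whose medians had opposite signs and stood apart from random lists in both lines, and the 5 most opposite single genes. Lists with opposite signs that stood apart in 1 line or in neither, such as the interferon-stimulated genes, are not included. With 1 library per group the difference between the lines was not tested, and dose and medium also differ with the line. Beyond the placement of their fixed lists, all tests of the ribosomal protein genes were chosen after the data were seen. For length, GC content and pseudogenes the prediction was written before the value of the test was seen.

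MHC class I antigen presentation genes had a median of −0.39 in DU145 and 1.13 in PC-3. CDK inhibitor genes had −0.40 and 0.62, with 1 of 14 higher and 2 lower in DU145, and 6 higher and 1 lower in PC-3. NF-kB targets had −0.28 and 0.45, with 1 of 28 higher and 6 lower in DU145, and 5 of 29 higher and 4 lower in PC-3. In DU145 CDK inhibitor genes no longer stood apart when matched on length and GC content, nor NF-kB targets under some alternatives. Under median-of-ratios scaling the DU145 medians of MHC class I, CDK inhibitor and NF-kB genes were −0.15, −0.17 and −0.05. On the deposited scale genes over 1 CPM in the DMSO library had a DU145 median of −0.19. Heat shock genes had 0.30 and −0.34, but in PC-3 their mean was 0.07, 4 of 18 were higher and 2 lower, and the list no longer stood apart under 2 alternatives. Of the 4 members that the rule for named genes gives, HSPA1A, HSPA1B and DNAJB4 were higher and HSPB1 lower in both lines. That rule ranks members by the mean of the 2 changes, which favours those that moved alike, so they do not speak for the list. Glycolysis and hypoxia genes had 0.51 and −0.28. Named members of the other lists also went both ways. CDKN1A (1.54 in DU145 and 2.35 in PC-3) and NDRG1 (1.05 and 2.21) were higher in both lines, and CXCL6 (−1.63 and −2.02) was lower in both. CDKN2B (−0.43 and 2.95) and HK2 (1.55 and −0.27) changed in opposite directions, as did the medians of their lists. Large-subunit ribosomal protein genes had −1.02 and 0.22, and small-subunit ones −0.46 and 0.29.

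Among single genes, SCEL, a protein of the cornified envelope, changed by 2.04 in DU145 and −1.91 in PC-3. C1S, a complement protease, changed by −1.85 and 2.30. KRTAP2-3, a keratin-associated protein with near-identical copies, changed by 1.70 and −2.07. BST2, the antiviral protein tetherin, changed by −1.49 and 3.68, and NGFR, a neurotrophin receptor, by −1.48 and 1.60.

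The lower ribosomal protein genes of the treated DU145 library were weighed against 3 technical explanations. Length and GC content do not account for it, since the median of the 78 genes, −0.92, lay at the 0.0th percentile of random lists matched on them. Reads moved to processed pseudogenes would raise those, but their CPM changed by −4.35% of what the genes lost, from 1646 to 1053 CPM. For per-million scaling, the first test left it open: the highest median under another scaling was −0.68 (bootstrap interval −0.80 to −0.27), and the interval crossed the bound of −0.3 set for it. So how much of the fall is scaling is not known. A second test, added because of that outcome, compared the genes with matched random lists under the other scalings (gap −0.988), but it decides nothing, since 1 factor moves both alike. On the deposited scale the median already lay −0.993 from that of such lists (−0.92 against −0.03 to 0.17 for 95% of them), and 1 factor for all genes does not give that gap. What stays open is a lower level of translation-related mRNAs in treated DU145 cells, as a hypothesis. Of these, 14 other mRNAs with 5-prime TOP sequences, chosen after the data were seen, had a median of −0.20. It lay at the 1.03th percentile of lists matched on expression (−0.14 to 0.31 for 95% of them). Ribosome biogenesis genes, a fixed list, had a DU145 median of −0.13 and did not stand apart, at the 6.84th percentile. A difference in RNA handling between the 2 libraries was not tested.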

How the results depend on the processing

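The design had named TMM scaling and edgeR for raw counts. Here they, and matching on length and GC content, were added after seeing the data. For DU145, median-of-ratios scaling gave 327 genes higher and 762 lower, TMM 251 higher, and a pseudocount of 0.1 gave 2640 genes (275 higher, 2365 lower). The scalings move the DU145 libraries against each other, and the smaller pseudocount shrinks low genes less. The PC-3 counts and those of genes changed the same way in both lines stayed within 1.5 times under each alternative. Genes higher in DU145 and lower in PC-3 went from 15 to 29 under median-of-ratios scaling, 23 under TMM and 27 with the smaller pseudocount, and those of the other direction from 49 to 28, 33 and 154. Across lines the counts of genes higher and lower were 8 and 83 under median-of-ratios scaling, 5 and 70 under TMM and 3 and 37 with edgeR. DESeq2 called 54 higher, limma without trend 7 higher, and the fit without a line term 0 higher and 0 lower, since the lines' own differences then enter the spread (230 genes at an unadjusted p under 0.05). Of the 191 calls, 91 were kept under median-of-ratios scaling, 75 under TMM and 40 with edgeR. The causes of the other differences were not tested. The DU145 median of oxidative phosphorylation genes reversed to 0.045 under median-of-ratios scaling. NF-kB targets in DU145 no longer stood apart under 3 alternatives, heat shock and pro-apoptotic genes in PC-3 under 2 each, and CDK inhibitor genes in DU145 under matching on length and GC content. Interferon-stimulated genes in DU145 came to stand apart, as lower, under both scalings and the smaller pseudocount. In DU145, XRCC2, LIG1, RPL35, RPS15, RPS15A, AHRR and CYP2S1 were under 2-fold under both scalings. Library totals alone are the deposited scale itself, and dropping the CPM minimum removes nothing, since a 2-fold change of log2(CPM + 1) needs 1 CPM. The main fit across lines pairs the libraries by line, and the fit without a line term is its unpaired form. With 1 library per group no library could be left out. Depth limits genes near 3 fragments, where intervals are wide.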

Other observations

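The tests here were chosen after the data were seen. For PC-3 reads in the DU145 control, and for length and GC content of the interferon-stimulated genes, the prediction was written before the value of the test was seen.

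Innate immune genes, named after their values were seen, were read in each line that listed them. Of these, IFIH1 is a member of the fixed list of interferon-stimulated genes, so it already counts in the medians of that list. The others lie outside the fixed lists. IFNL1 and IFNL3 had no value in DU145, and IFNA1 had none in PC-3. In PC-3 IFNB1, which encodes interferon beta, had 3 fragments with DMSO and 24 with OICR-9429, IFNL1 had 2 and 9, and IFNL3 had 0 and 5. In DU145 IFNB1 had 2 and 6 fragments and IFNA1 2 and 17, while the interferon-stimulated genes there had a median of −0.28. IFNE stood at 2.12 and 5.61 CPM in PC-3 and at 1.12 and 2.32 CPM in DU145. IFIH1, the cytoplasmic sensor of double-stranded RNA, stood at 11.8 and 158 CPM in PC-3 and at 23.1 and 21.6 CPM in DU145, and TLR3, an endosomal sensor, at 2.01 and 7.09 CPM in PC-3. The DNA sensor CGAS stood at 19.1 and 14.4 CPM and its adaptor STING1 at 19.4 and 15.9 CPM in PC-3. In DU145 TLR3 stood at 3.62 and 4.11 CPM, CGAS at 31.1 and 33.8 CPM and STING1 at 66.9 and 42.0 CPM. In PC-3 IFNB1, IFNL1 and IFNL3 together had 5 fragments with DMSO and 38 with OICR-9429, a depth-corrected ratio of 8.01 (3.15 to 26.1, counting error only). These genes were picked from the values themselves, so the ratio restates them and decides nothing about the cause of the higher interferon-stimulated genes.

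The higher interferon-stimulated genes of the treated PC-3 library were weighed against 3 technical explanations. Leukocytes would bring their abundant transcripts, but the highest leukocyte marker in that library, PTPRC, stood at 0.432 CPM, against 0.580 CPM with DMSO. DU145 reads cannot raise a gene above its DU145 level, and 28 of the 35 genes stood above both DU145 libraries in the treated PC-3 library and not in the control. Length and GC content do not account for it, with the median at the 100th percentile of lists matched on them. A response of PC-3 cells to the compound stays open as a hypothesis, without a replicate.

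Genes under 10 CPM were lower in the treated DU145 library. Scaling by 1 factor would move all levels by the same ratio of CPM, and on the log2(CPM + 1) scale low genes less than high ones. But the low genes fell more: the median of genes at 1 to 10 CPM lay −0.47 from that of genes over 100 CPM (bootstrap interval −0.49 to −0.44). Unspliced background in the control stays open. Under 1 CPM the log2 ratio of summed CPM, OICR-9429 to DMSO, was −0.45 for single-exon genes and −0.82 for multi-exon protein-coding genes. The difference of −0.37 (−0.44 to −0.30) passed the bound written against background. It does not exclude background, which may add more to longer transcripts, and how the fall depends on length was not tested. PC-3 reads in the control would lower genes that are high in PC-3, but these lay 0.15 above other genes of the same level (−0.02 to 0.31). A difference in library complexity and an effect of the compound both stay open, as neither was tested.

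Across the 78 ribosomal protein genes the DU145 changes fell into 42 at −0.8 or below, 28 above −0.4 and 8 between. The changes were correlated between the lines, but the genes lowest in DU145 were not lower with OICR-9429 in PC-3 as a set: the 42 had a PC-3 median of 0.16 and the rest 0.42. Spearman's rho between the changes was 0.49 and Pearson's r 0.42 (two-sided permutation p = 1e-05, the smallest 100000 permutations can give, and 0.0001). The rho was 0.56 without the 2 genes farthest from the DU145 median and 0.52 over the 69 genes of at least 30 CPM. With expression level, length and GC content removed by rank the partial correlation was 0.47 (permutation p = 1e-05, also 1e-05 adjusted over the 2 rank correlations by Benjamini-Hochberg). These are correlations across genes, which are not independent replicates. A shared regulation of a subset of these genes is 1 hypothesis, and a library or mapping effect common to them another, which may equally give a rho of 0.49.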
